A study of Pseudomonas cichorii JBC1 with 2 samples.

How the data were processed

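Gene expression was measured by RNA sequencing in Pseudomonas cichorii JBC1, a bacterium that causes disease in plants. Per the labels' protocols, the strain was grown in LB medium and then kept for 12 hours in minimal medium, shaken at 30 °C, either under green light or in the dark. RNA was taken with TRI reagent, an acid phenol mixture, and libraries followed a standard Illumina preparation. Per the labels, 3 cultures of each condition were pooled before sequencing, so each condition has 1 library and there is no replicate. Whether the libraries kept the strand of the RNA is not stated, so reads of overlapping genes on opposite strands cannot be separated.

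The submitters' processing notes name Bowtie, a read aligner, without a version. The counting tool and the genome build are not given in the sources used here. The headers of the deposited gene tables state no unit, so units were taken from the tables' titles and checked on the values. The authors deposited a raw count of reads per gene for each library, in whole numbers. A second deposited table holds a normalized signal per gene, titled as scaled by relative log expression (RLE). Its values equalled the counts times 1.19 in the dark library and times 0.840 in the green-light library. Another deposited table is titled as RPKM per gene, that is reads scaled by gene length and by library total. The values imply that the authors used a gene length about 49.8 bases shorter than the distance between its coordinates. A deposited summary of the quartiles of these values, with 8 columns of values per library and scaling, was not used here.

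Each table lists 5258 genes by locus tag, product name and coordinates, of which 5174 code for proteins. The other 19 ribosomal RNA genes and 65 transfer RNA genes had 0 reads in both libraries and were left out. The tables pair no gene symbols with the locus tags. Total counts were 8799511 in the dark library and 12020270 in the green-light library, with a median of 492 and 692 reads per protein-coding gene.

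Counts were divided by median-of-ratios size factors over protein-coding genes with reads in both libraries, 0.840 for dark and 1.19 for green light. The log2 ratio of green light to dark was taken after adding 0.5 normalized reads to each value. Genes with fewer than 50 reads summed over the 2 libraries were left out of the comparison, which left 4989. With 1 library per condition no test and no p-value was possible, and a gene was counted as different by size, at 2-fold or more. Each ratio carries an exact (Clopper-Pearson) 95% interval from the gene's reads. These intervals cover counting error only, since reads are not independent molecules and differences between cultures are not in them.

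On simulated counts with the depths of these libraries, all 100 genes set to a 3-fold change and all 100 set to a 4-fold change were recovered past 2-fold. Of 4787 unchanged genes, 1 passed 2-fold, among 4987 genes in that comparison of green light against dark. The simulated counts held counting error only, without differences between cultures or libraries. They give no error rate for the differences in the real data.

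There were 37 gene lists, fixed before the data were examined and matched on words of the product name. A list with at least 5 measured genes was set apart when its median log2 ratio lay under percentile 2.5 or over percentile 97.5 of 10000 random lists. The random lists had the same size and were matched on mean expression in 10 bins. Some short patterns also hit parts of longer words, so that the list for the SOS response took in 332 genes and the phosphate list 72. A narrower match, at the start of a word and with gene symbols as whole words, was added after the data were seen and gave 22 and 14 genes. The housekeeping list named only symbols and matched no gene, so its genes were found by product name after the data were seen. Runs of neighbouring genes are 4 or more successive measured genes in order of start position that all differed by 2-fold or more in 1 direction. Start position was used because the locus tags break that order at 50 places. Their number of genes was set beside 10000 random orders of the same genes.

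The genes named were chosen by a rule fixed before the data were examined. It took the 12 highest and 12 lowest log2 ratios among genes with at least 100 summed reads, the 3 most different members of each list, every member of the light sensing and photolyase lists, the members of the 5 longest runs, and the housekeeping genes. Any other gene named was chosen after its values were seen. Alternatives were scaling by total reads or by TMM (edgeR 4.0.16 in R 4.3.3), the deposited normalized values, other read minimums, pseudocounts, size rules, list matches and run lengths. Other computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.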

Results

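RNA of Pseudomonas cichorii JBC1 was sequenced after 12 hours in minimal medium under green light or in the dark, to ask how green light bears on the transcriptome of this plant pathogen. There was 1 library per condition, each from 3 pooled cultures, with 12020270 reads on genes under green light and 8799511 in the dark. Of 5174 protein-coding genes, 1 had 0 reads under green light and 6 had 0 reads in the dark. Coordinates are those of the deposited tables, on the single chromosome they list, for a genome build that is not named. The differences have no replicate check, and the brackets after each fold hold the exact 95% counting interval.

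Under green light, 61 of 4989 measured genes were at least 2-fold higher and 130 were at least 2-fold lower, while 4798 (96.2%) lay within 2-fold. The highest ratios belonged to ABC transporter genes, and most of the 12 lowest to a single stretch of metabolic genes. At 4-fold or more, 15 genes were higher and 25 lower. Hypothetical proteins made up 19 of the 61 higher and 61 of the 130 lower genes. The log2 ratios had an SD of 0.44 across genes. For 44 of the higher and 93 of the lower genes the whole counting interval lay beyond 2-fold.

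**Figure D1:**
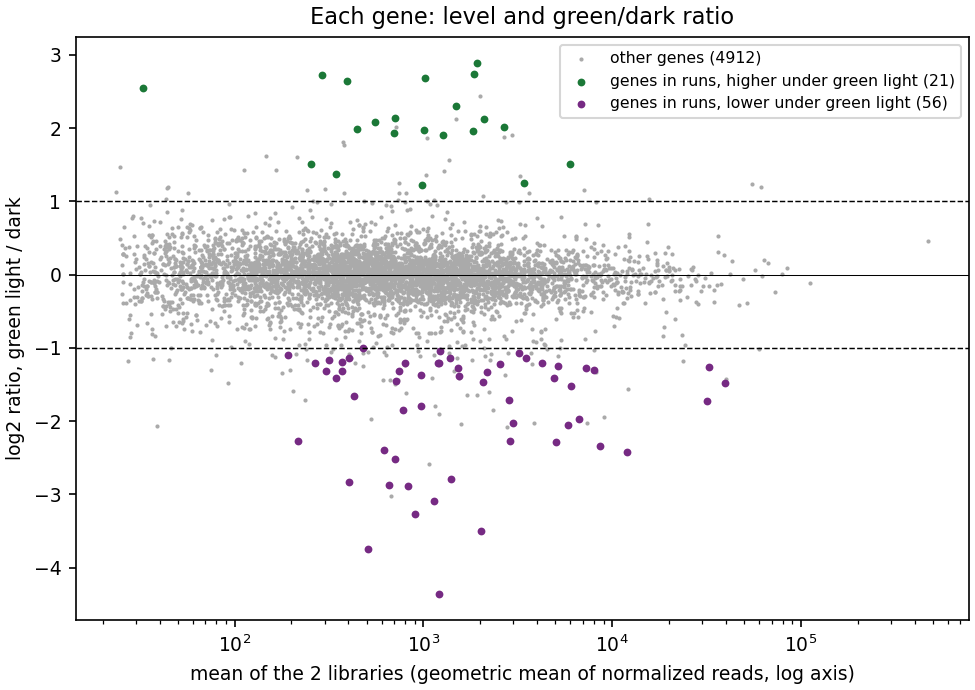
Log2 ratio of green light to dark (vertical axis) against the geometric mean of normalized reads of the 2 libraries (horizontal log axis), 1 point per measured gene, with dashed lines at 2-fold. The 21 genes in higher runs (green) and the 56 in lower runs (purple) lie beyond the lines at low and high expression, and most of the 4989 genes lie between them.

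The gene for the sigma factor RpoE (PCH70_01350, 145808 to 146416) was 4.35-fold higher under green light [3.99 to 4.75], with 600 reads in the dark and 3704 under green light. Sigma factors direct RNA polymerase to particular promoters. The adjoining gene, annotated as the transcriptional activator ChrR (PCH70_01360), had a log2 ratio of 1.86. A stretch of 7 genes, PCH70_08960 to PCH70_09020 (994731 to 1001186, minus strand), was higher throughout, with log2 ratios between 1.51 and 2.30. It holds the gene for deoxyribodipyrimidine photolyase (PCH70_09020), an enzyme that uses light to repair ultraviolet damage in DNA. That gene was 2.84-fold higher [2.73 to 2.96] and was the only photolyase matched in the tables. The others in the stretch include a cyclopropane-fatty-acyl-phospholipid synthase (PCH70_08970, log2 ratio 2.02), which modifies membrane lipids, a flavin-containing amine oxidase (PCH70_08990, 2.13) and a short chain dehydrogenase (PCH70_09000, 2.30). Neighbouring genes here overlap by a few bases on the same strand.

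Further genes among the 12 highest encode transport proteins. An ABC transporter ATP-binding protein (PCH70_51530, 5959888 to 5961189) was 7.39-fold higher [6.79 to 8.05], and the transport membrane protein beside it (PCH70_51540) had a log2 ratio of 2.74. They belong to a run of 5 genes with a sensor histidine kinase (PCH70_51520, 1.96) and a LuxR-type response regulator (PCH70_51510, 1.91), which overlaps PCH70_51500 on the opposite strand. A cation ABC transporter (PCH70_24330, PCH70_24340 and PCH70_24350, within 2759664 to 2762185) had log2 ratios of 2.65, 2.72 and 2.68 from 131, 95 and 339 reads in the dark. A gene annotated as TMAO/DMSO reductase (PCH70_08300) had a fold interval of 4.57 to 5.47 and a log2 ratio of 2.32. The hypothetical protein PCH70_30270 had a log2 ratio of 2.44.

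The list of light sensing genes matched 3 genes, all annotated as heme oxygenase, an enzyme that opens the haem ring to the bilin pigments that phytochromes bind. PCH70_14460 (1600455 to 1601069) was higher under green light with a log2 ratio of 1.12 and a fold interval of 1.95 to 2.42. The other two, PCH70_10510 and PCH70_20260, had log2 ratios of -0.08 and 0.27 from 52 and 78 reads in the dark, and no difference was detectable at this depth. The gene that overlaps PCH70_14460 by a few bases on the same strand, a GAF-domain histidine kinase (PCH70_14470, named after its values were seen), had a log2 ratio of 1.11.

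The lowest ratios under green light came from 13 neighbouring genes, PCH70_19050 to PCH70_19170 (2136554 to 2148078, minus strand), whose median log2 ratio was -2.88. A putative dehydrogenase (PCH70_19160) was 20.5-fold lower [18.3 to 23.1], with 4583 reads in the dark and 317 under green light. The log2 ratios were -3.75 for PCH70_19170 and -3.49 for PCH70_19150, and reached -1.79 and -1.45 for PCH70_19060 and PCH70_19050 at the other end. The stretch also encodes a fatty acid desaturase (PCH70_19100, -2.88) and a methylthioadenosine phosphorylase (PCH70_19090, -2.78). The genes on either side had log2 ratios of -0.71 (PCH70_19040) and -0.15 (PCH70_19180). Of the other lowest genes, the hypothetical proteins PCH70_33020 and PCH70_33030 had log2 ratios of -3.02 and -2.58.

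**Figure D2:**
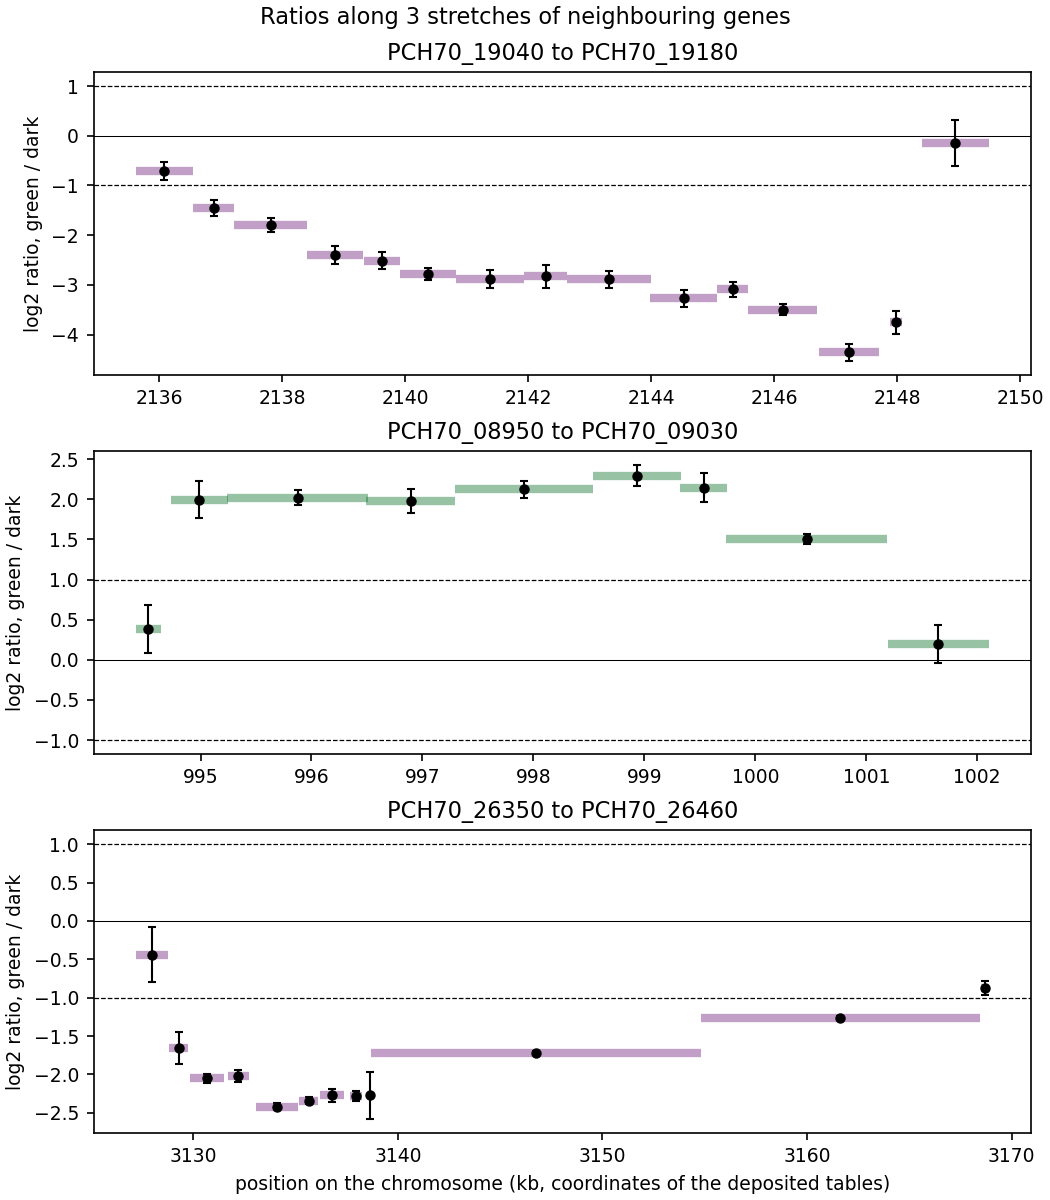
Log2 ratio of green light to dark (vertical axis) along the chromosome (horizontal axis, kb) for the genes of 3 runs and the measured gene on each side. Coloured bars span each gene, points mark its ratio, and error bars are exact 95% counting intervals; within PCH70_19050 to PCH70_19170 the ratios run from -1.45 to -4.36.

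The list for nonribosomal peptide synthesis, in which large enzymes assemble peptides without ribosomes, stood apart as lower. Of 16 listed genes, 6 were at least 2-fold lower and 0 higher, with a median log2 ratio of -0.33 (percentile 0.03 of random lists). The list was split, with 6 genes above 0 and 10 below. Scaled by total reads, or in the deposited RPKM values, 8 were above 0 and 8 below. The synthetase genes PCH70_25300 (2884783 to 2913774) and PCH70_26390 (3133049 to 3135136) were 2.78-fold [2.74 to 2.82] and 5.35-fold [5.20 to 5.50] lower. PCH70_26110, beside the regulator SyrR (PCH70_26120, -1.33), had a log2 ratio of -1.56. Synthetases annotated for the siderophores pyoverdine and yersiniabactin, 6 genes, had log2 ratios between -0.02 and 0.41. With the narrower match the list held 18 genes, 8 of them at least 2-fold lower, and its median was -0.68. Its 13 genes of at least 3000 bases had a median of -0.02, with 5 at least 2-fold lower. Its 5 shorter genes had a median of -1.33, with 3 at least 2-fold lower. The large synthetase genes were therefore not lower as a class.

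Some of these synthetase genes sat within longer lower runs. PCH70_26360 to PCH70_26450 (10 genes, 3128807 to 3168439, median -2.16) holds SyrP (PCH70_26380, -2.02), a chlorinating enzyme (PCH70_26400, -2.34) and a cyclic peptide transporter (PCH70_26370, -2.05). PCH70_25230 to PCH70_25300 (8 genes, median -1.43) holds efflux genes and a diaminobutyrate transaminase (PCH70_25240, -1.52). The LuxR-type regulators PCH70_25350 and PCH70_25390 nearby had log2 ratios of -2.03 and -2.08. A run of 11 genes, mostly hypothetical, PCH70_26780 to PCH70_26880, had a median of -1.25. In all, 77 genes lay in 11 runs, 4 higher and 7 lower. Random orders of the same genes gave 0.0064 genes in runs on average and at most 4. Bacterial neighbours are often transcribed together and random orders separate them. The contrast therefore shows only that neighbours differed together, and not why.

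Across the lists, 11 of the 34 with enough genes stood apart, 5 higher and 6 lower. By chance 1.7 would, if genes varied independently. Some lists share genes or hold neighbours that moved together, so chance alone could give more. The random lists were not matched on chromosome position either. Genes around the start of the chromosome map exceeded those opposite by 0.13 in median log2 ratio. Several lists that stood apart had medians no larger than this, and a part of position in them was not tested. Type VI secretion, a contractile device that injects proteins into other cells, was lower, with 18 of 20 listed genes below 0. The median log2 ratio was -0.38, and none of the 20 passed 2-fold. The most different listed gene, PCH70_21160, was 1.94-fold lower [1.86 to 2.03]. Hcp and Vgr proteins are also parts of this device. Of 15 genes named Hcp, Vgr or Rhs, 7 were at least 2-fold lower, and the list left those 7 out. All 5 cold shock genes were below 0 (median -0.40), led by CapB (PCH70_39600, -0.76). All 13 genes of the NADH dehydrogenase complex, the entry point of the respiratory chain, were below 0 (median -0.26), led by subunit B (PCH70_18240, -0.39). Scaled by total reads, or in the deposited RPKM values, 1 of the 13 was above 0. Those 13 genes lie next to one another, so the list could not be judged with 1 value per stretch of neighbours. Oxidative stress defence was lower as a list (43 genes, median -0.13), though 16 of the 43 were above 0. A catalase (PCH70_32530) was 2.67-fold lower [2.48 to 2.87]. The 1 gene at least 2-fold higher was the photolyase PCH70_09020 (1.51), matched through part of its product name, and the narrower match leaves it out (30 genes, median -0.14, percentile 1.36). Type III secretion was lower too (19 genes, median -0.15, percentile 1.81). With the narrower match it no longer stood apart (percentile 3.19).

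Of the lists that were higher, alternative sigma factors had a median log2 ratio of 0.16 over 34 genes, 26 of them above 0, and only RpoE passed 2-fold. Siderophore, TonB and iron uptake genes had a median of 0.13, with 62 of 88 above 0. Of these 1 passed 2-fold, a putative siderophore receptor (PCH70_20200), 3.52-fold higher [2.98 to 4.17]. Genes near it outside the list were also higher. They were a nickel transport binding protein (PCH70_20190, 1.42), a carbonic anhydrase-related protein (PCH70_20170, 1.61) and, less so, PCH70_20180 (0.45). Which metal this receptor serves was not examined. Flagella and chemotaxis genes had a median of 0.12, with 61 of 86 above 0. The chemotaxis transducer PCH70_01190 was 3.69-fold higher [3.47 to 3.93], and the methyl-accepting chemotaxis protein PCH70_36290 was 4.10-fold lower [3.80 to 4.42]. The tricarboxylic acid cycle list had a median of 0.12 over 28 genes with none past 2-fold. ABC transporters had a median of 0.06 over 222 genes, 4 higher and 2 lower by 2-fold. With 1 value per stretch of neighbours these last 2 lists were at percentiles 96.9 and 96.7 and no longer stood apart. When the narrower match was used as well, the tricarboxylic acid cycle list did stand apart (percentile 98.8).

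**Figure D3:**
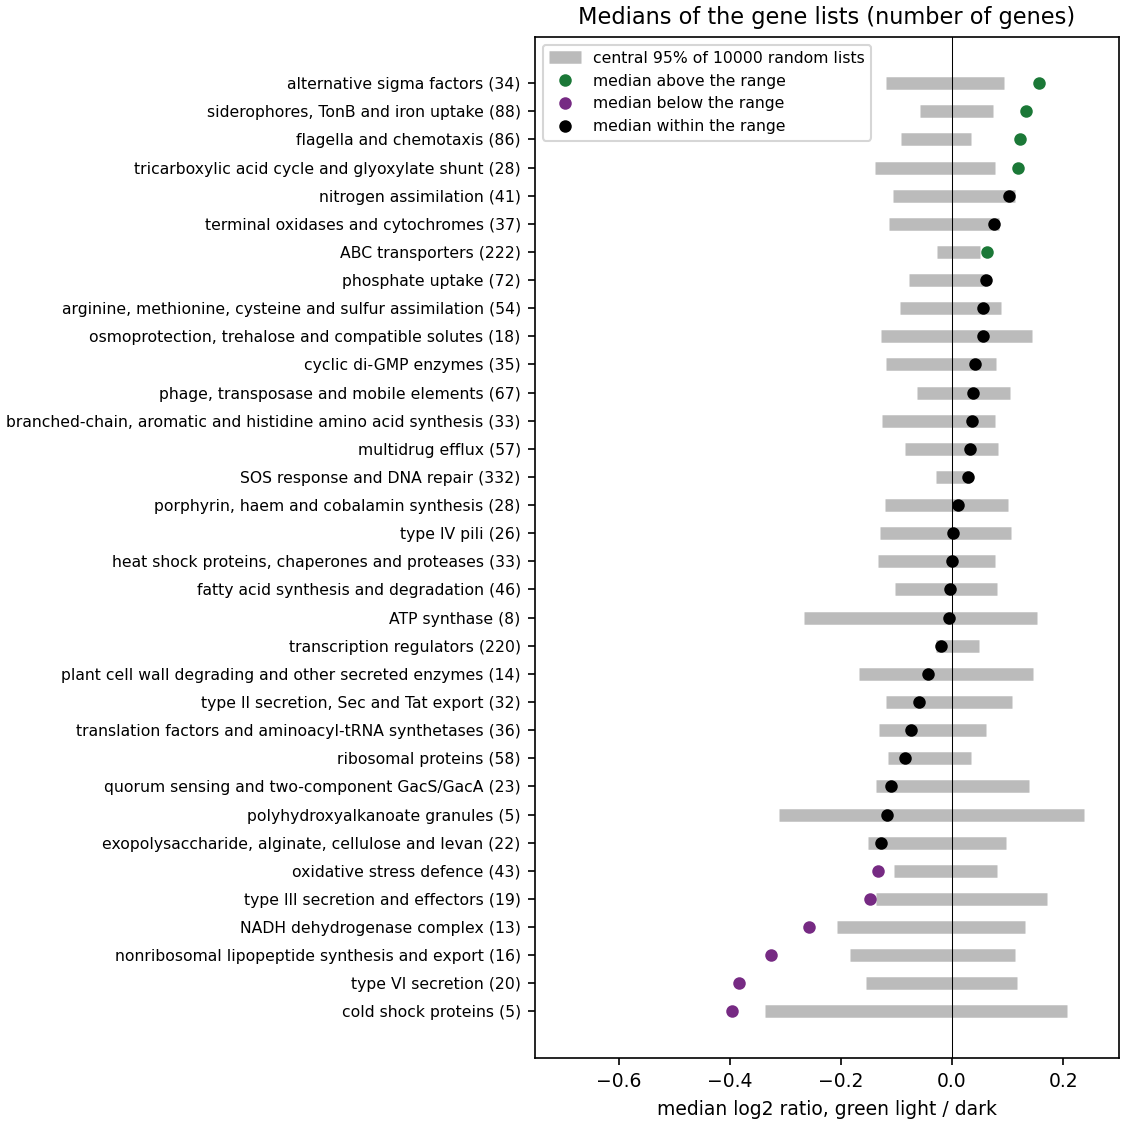
Median log2 ratio of green light to dark (horizontal axis) of each gene list with at least 5 measured genes, with the number of genes after its name. Grey bars hold the central 95% of medians of 10000 random lists matched on expression; 5 medians lie above their bar (green) and 6 below (purple).

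Other lists did not stand apart as fixed. Ribosomal proteins had a median of -0.09 over 58 genes, though the L31 type B protein (PCH70_40210) had a log2 ratio of 1.62 from 70 and 307 reads. ATP synthase genes had a median of -0.01. The SOS list had a median of 0.03 as fixed and -0.07 with the narrower match. The phosphate list had a median of 0.06 as fixed (percentile 97.4), and with the narrower match 14 genes had a median of 0.38 and stood apart. So did terminal oxidases and cytochromes (40 genes, median 0.09, percentile 98.3) and nitrogen assimilation (40 genes, median 0.13, percentile 98.6), which as fixed were at percentiles 96.2 and 95.7. With 1 value per stretch of neighbours and the narrower match, these 2 lists no longer stood apart (medians -0.02 and 0.12, percentiles 42.7 and 96.3), while the phosphate list still did (99.9). Of 22 exopolysaccharide genes, 4 for alginate synthesis were at least 2-fold lower, among them AlgK (PCH70_10100, -1.31), AlgE (PCH70_10090, -1.14) and Alg44 (PCH70_10110, -1.19). In the same cluster AlgG (PCH70_10080), outside the list as fixed, had -1.01, while AlgF (PCH70_10030, 0.53) and AlgJ (PCH70_10040, 0.18) were above 0. The heat shock list had a median of 0.00, and HtpX (PCH70_37220), a membrane protease, was 2.22-fold higher [2.14 to 2.30]. Class I lysyl-tRNA synthetase (PCH70_16400) was 4.09-fold lower [3.90 to 4.29]. The 10 housekeeping genes had log2 ratios from -0.39 to 0.26.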

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

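The scalings and filters below were planned before the data were examined, and the narrower list match, the total without the most abundant gene and the single value per stretch were added afterwards. No paired analysis was possible because each condition has 1 library, made from pooled cultures. At 1.5-fold, 176 genes were higher and 312 lower under green light, and at 3-fold 27 were higher and 43 lower, which follows from the size rule itself. Under the other alternatives the 61 higher genes became 44 to 83 and the 130 lower genes 93 to 141. Genes in runs numbered 55 to 92 against 77. The 11 lists became 8 with 1 value per stretch of neighbours and 13 with the narrower match. Scaling by total reads gave 72 higher and 119 lower genes and a median log2 ratio of all genes of 0.06, and list medians moved with it. The ABC transporter median went from 0.06 to 0.12, and to 0.14 without the most abundant gene. The oxidative stress median went from -0.13 to -0.08 and -0.05. No direction was reversed among 405 values of the 81 named genes past 2-fold, and 2 of the values dropped under 2-fold. These settings rescale all genes alike or change the pseudocount, so genes past 2-fold could hardly change direction. The 405 values are therefore no independent checks. Depth limits genes near the minimum of 50 summed reads most, and no alternative replaces the missing replicates.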

Other observations

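The gene groups and tests in this part were chosen after the data were seen, except the tests of gene length and of chromosome position. Of 15 genes named Hcp, Vgr or Rhs, 7 were at least 2-fold lower under green light and 0 higher, and 2 were above 0. Their median log2 ratio was -0.78, with no comparison to random lists. The Hcp genes PCH70_03320 and PCH70_09910 had log2 ratios of -1.97 and -1.94, and reads shared between these like-named copies cannot be excluded. Vgr genes at other loci differed, with -1.90 for PCH70_00950 and 0.21 for PCH70_23960. Of 39 genes with chemoreceptor product names, 2 were higher and 2 lower by 2-fold. PCH70_30270, a hypothetical protein by product name with a log2 ratio of 2.44, is outside this count but carries the same KEGG identifier as the chemotaxis transducer PCH70_01190, as does PCH70_17420 (BdlA, log2 ratio 1.34).

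Of the 14 phosphate genes by the narrower match, 12 were above 0 and 0 passed 2-fold. PCH70_19930, PCH70_19950 and PCH70_19920 had log2 ratios of 0.99, 0.80 and 0.79, and PCH70_50930 had 0.57. A response regulator (PCH70_38280), its sensor kinase (PCH70_38270) and the hypothetical protein PCH70_38290 were abundant and higher, with log2 ratios of 1.23, 1.04 and 1.19. The gene with the most reads, PCH70_16610, annotated as a cbb3 oxidase subunit, took 3.84% of reads in the dark and 5.49% under green light. Its level in the dark was 42557 RPKM, against 2400 for PCH70_16620, the oxidase gene next to it. Whether all these reads come from the annotated gene is not known. Its log2 ratio was 0.46, while PCH70_16620 and the oxidase genes PCH70_16630 and PCH70_16640 had -0.30, -0.24 and -0.23.

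RpoE, ChrR and the photolyase run were higher together. In other bacteria RpoE and ChrR are known as a pair that answers singlet oxygen, which light and a photosensitizer can form. Of 11 genes with product names tied to such a response, 8 were at least 2-fold higher, and 3 amine oxidases (PCH70_09060, PCH70_36170 and PCH70_47670) had log2 ratios of 0.35, -0.18 and 0.00. The names were picked knowing the values, so this count is no test, and such a response stays untested. A general rise of the listed oxidative stress genes is argued against, since that list lay at percentile 1.36 of random lists. By the narrower match 10 of its 30 genes were above 0. Its patterns also cover thioredoxins and glutaredoxins, so it is wider than peroxide and superoxide defence. Defence genes whose product names hold none of its words are not in it and were not judged. Its percentile was known when this question was set, so it is no separate test. Heat shock and chaperone genes lay at percentile 63.8 with a median of 0.00. A difference between pools unrelated to light stays open, because there was 1 library per condition.

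By the narrower match, 8 of 18 peptide synthetase and associated genes were at least 2-fold lower. Reads lost from long genes are argued against: 104 genes of at least 3000 bases outside the list and the runs had a median log2 ratio of 0.0083. Their quartiles were -0.13 and 0.14. Leaving out runs drops some long genes for being 2-fold lower, such as PCH70_25270 (-1.39). Within the list, the 13 genes of at least 3000 bases had a median of -0.02 and the 5 shorter ones -1.33. Lengths far above 3000 bases, such as 30852 for PCH70_25320, were not judged separately. Genes around the start of the chromosome map exceeded those opposite by 0.13 in median log2 ratio (95% bootstrap interval 0.08 to 0.18). The bounds set beforehand were 0.3 or more for a difference in replication large enough to change gene dosage, and under 0.1, interval included, against it. Neither was met, so such a difference stays open. The 8 lower genes, all in the tenth of the chromosome opposite, had log2 ratios from -2.42 to -1.18. The 95 other genes between them, outside the runs, had a median of -0.19 (95% bootstrap interval -0.32 to -0.06). Leaving out runs drops genes for being 2-fold lower, which raises this median. The genes dropped belong to the run of 10 genes PCH70_26360 to PCH70_26450, and the lower quartile of the 95 was -0.41. Both bootstrap intervals drew genes singly, although neighbours move together, and hold no differences between cultures, so they may be too narrow. Gene dosage acts on neighbouring genes alike, so as the whole cause it is argued against, and a part in the pattern stays open. A difference between pools unrelated to light, such as cell density, may also account for the pattern and stays open with 1 library per condition.

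In PCH70_19050 to PCH70_19170 the highest and lowest log2 ratio differed by 2.91, with counting intervals that do not overlap. Loss of the whole region from part of the green-light cells would by itself give its genes 1 shared ratio. As the whole cause it is argued against, and a part in the pattern stays open. The ratios were known when this question was set, so it is no separate test. The ratio was lowest toward PCH70_19160 and PCH70_19170, the upstream end on the minus strand. No biological explanation was tested. A difference between pools unrelated to light stays open with 1 library per condition.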
